A study of Homo sapiens with 6 samples.

How the data were processed

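RNA was measured in 6 libraries of WM266.4 melanoma cells, 3 from cells given non-targeting siRNAs (siCtrl) and 3 from cells given siRNAs against DNMT1 (siDNMT1). Per the labels' protocols, the cells grew in DMEM with 10% FBS, were transfected on day 0, subcultured on day 2, transfected again on day 3 and harvested on day 7. Polyadenylated RNA was made into libraries with a directional kit and sequenced from both ends on an Illumina HiSeq, per the labels' protocols. The submitters' processing notes name Trim Galore 0.5.0, TopHat2 2.0.9, Cufflinks 2.1.1 and the build hg19. Their options, the gene annotation and whether the counting used strand are not given in the sources used here, so rows that overlap a row on the other strand are named as overlapping.

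Each deposited table gave 1 library and listed a gene symbol, a locus and an FPKM (fragments scaled by transcript length and by library size) that the authors had computed, per the file headers. The 23975 rows were in the same order in each table. Locus starts were taken as counted from 0 and had 1 added, because the span of 1182 of 1289 microRNA rows then equalled the gene length in RefSeq. There were 310 symbols on several rows (695 rows in all), which were kept as separate rows. A gene list took the row with the highest mean.

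An exact 0 can be a failed estimate in these tables. ILF3, a gene of most cells, was listed at 0 in 5 libraries and at 63.5 FPKM in siDNMT1 replicate 01, and HNRNPD and PLEC were listed at 0 in 1 library each (siCtrl replicate 02 and siDNMT1 replicate 02) beside at least 129 and 73.4 FPKM in the others of the group. In 42 rows, 37 of them small RNAs, a 0 stood beside at least 5 FPKM in the same group. A gene at 0 is therefore described as listed at 0, with the value of each library and no fold change. Total FPKM ranged from 365595 to 458114, of which small RNA rows held 0.120% to 9.58%. Without those rows the totals were 409998 to 415587 in siCtrl and 362055 to 375964 in siDNMT1. FPKM hold no read counts, so the depth is unknown. Relative depth was read from the commonest ratio of values under 0.05 FPKM between libraries, and lay between 0.963 and 1.09.

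Values were transformed as log2(FPKM + 1), with rows kept at a mean of at least 0.5 FPKM over the 6 libraries. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated test with a variance trend) and Benjamini-Hochberg adjustment, at an adjusted p of 0.05, and counts were also taken at an absolute change of at least 1 log2 unit. Folds are ratios of mean FPKM. In simulated data with the means and spread of the 13058 tested rows and 200 changed genes, the siDNMT1 against siCtrl test recovered 93% of genes changed by 0.5 log2 units and 99% of those changed by 1, and 2.04% of its calls were false. The real data had 9190 calls, and the simulation held no shift of scaling between libraries. Its rates therefore do not cover calls that turn on the scaling. The changed genes were drawn from rows with a siCtrl mean above 1 in log2(FPKM + 1), so the recovery rates do not cover lower rows. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

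Before the data were examined, 20 gene lists were fixed: DNA methylation machinery, X-linked cancer-testis genes, autosomal germline genes, type I interferon response, antigen presentation, p53 target genes, DNA replication and G1/S, G2/M and mitosis, melanocyte lineage, invasive or dedifferentiated melanoma, inflammatory and senescence-associated secreted factors, MAPK pathway output, imprinted genes, genes with reported promoter methylation in melanoma, HOX genes, endogenous retrovirus-derived genes, amino acid and ER stress response, housekeeping control genes, markers of other cell types, and RNA quality and library composition. The 19 with at least 3 members past the filter were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The rule for named genes, fixed at the same time, took DNMT1, the 10 largest increases and 10 largest decreases past the threshold with groups that did not overlap, and up to 4 members past the threshold with the largest change from each list. A list with none past it gave the 2 members with the highest mean. Symbols of small RNAs, LINC and LOC rows were tested and not named. Text naming a gene outside the rule says so, or the gene is given as an exception to a count or to a scaling; all such genes were chosen after their values were seen.

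Alternatives fixed at the same time were pseudocounts of 0.1 and 0.5, no filter, filters at a mean of 1 and 5 FPKM, rescaling to TPM, median-ratio scaling over genes with a mean of at least 1 FPKM, quantile normalization, no variance trend, a robust prior, array weights, the replicate number as a block, each library left out, and rows of a symbol summed. Alternatives added after seeing the data left out small RNA rows, left out the 42 rows above, left DNMT1 out of its list, and removed the trend of each library on transcript length. Lengths were those of the longest GENCODE transcript and were found for 92.2% of tested rows. Tests made for count tables were planned for the case that the tables held counts and were not run, since they hold FPKM.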

Results

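Transcripts were measured by RNA sequencing in WM266.4 cells, an established human melanoma line with a mutant BRAF gene and loss of a PTEN copy, in a derivative that stably expresses EGFP and firefly luciferase. The series held 6 libraries. In 3 of them the cells had received a pool of non-targeting siRNAs (siCtrl), and in the other 3 a pool of siRNAs against DNMT1 (siDNMT1), the methyltransferase that copies DNA methylation onto the new strand after replication. The siRNAs were given on day 0 and day 3, and RNA was taken on day 7. The labels call the libraries of each group triplicates without saying whether they came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. The deposited values were FPKM for 23975 gene rows, of which 4912 were listed at 0 in every library and 13058 had a mean of at least 0.5 FPKM and were tested. FPKM do not keep the number of fragments. The spacing of the lowest values put the depth of the other libraries at 0.963 to 1.09 times that of siCtrl replicate 01. Across the tested genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) was at least 0.984 between libraries of a group and at most 0.954 between libraries of different groups.

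The comparison asked which transcripts depend on DNMT1 in these cells. DNMT1 itself (hg19 chromosome 19, 10244022 to 10305755) stood at 51.3, 53.4 and 52.5 FPKM in the siCtrl libraries and at 4.81, 4.70 and 5.17 FPKM in the siDNMT1 libraries. The siDNMT1 libraries kept 9.34% ± 0.48 (SD, n = 3) of the control mean. The change in log2(FPKM + 1), the scale of all log2 changes given here, was -3.18 (SE 0.044, limma adjusted p = 5.8e-10). This scale understates the change of genes with low values. For DNMT1 alone the exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow.

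**Figure D1:**
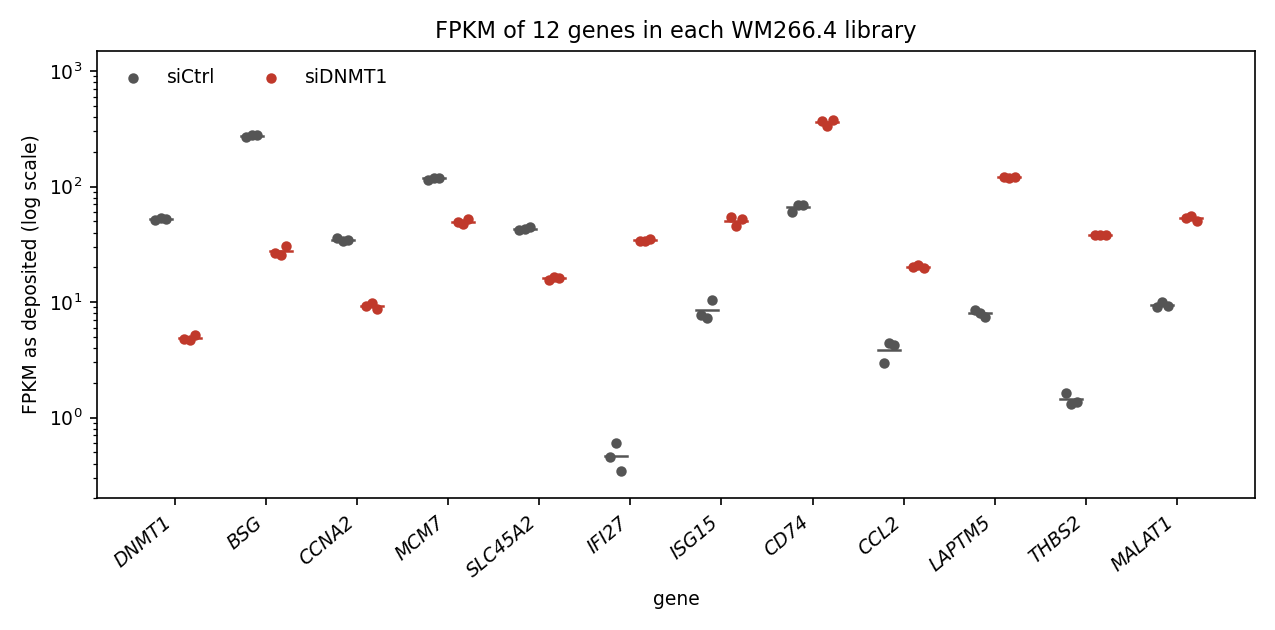
FPKM (log scale) of 12 genes in each siCtrl (grey) and siDNMT1 (red) library, with a bar at the mean of each group of 3. DNMT1, BSG, CCNA2, MCM7 and SLC45A2 lay lower in the siDNMT1 libraries, and IFI27, ISG15, CD74, CCL2, LAPTM5, THBS2 and MALAT1 lay higher, with no overlap between the groups.

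Much of the transcriptome differed between the groups. As deposited, 3175 gene rows were higher and 6015 lower in siDNMT1 (limma, adjusted p under 0.05), and 354 were higher and 258 lower by at least 1 log2 unit. In 9659 rows (74.0%) every value of one group lay beyond every value of the other, which chance gives in 10% of rows. The split between directions depended on the scaling of the libraries. It was 4583 higher and 4259 lower with median-ratio scaling, 4715 and 3136 after rescaling to TPM, 3933 and 4734 with quantile normalization, and 4540 and 4464 with a trend on transcript length removed, the last chosen after seeing the data. The median log2 change of all tested rows was -0.11 as deposited, 0.02 with median-ratio scaling and 0.07 as TPM. Counts within lists are therefore also given for other scalings where these moved the balance of directions. The totals used for TPM included the small RNA rows, whose share differed between libraries. Counts and small changes given as TPM, here and below, therefore depend in part on those rows. TPM without them was not computed. The count lower by at least 1 log2 unit was 147 with median-ratio scaling.

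**Figure D2:**
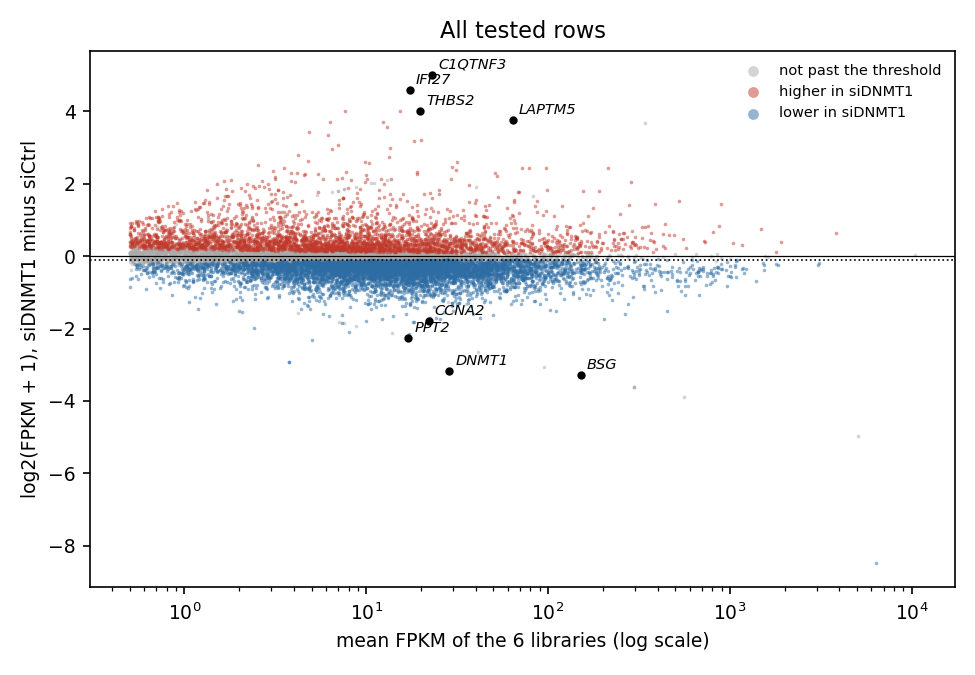
Log2 change (siDNMT1 minus siCtrl) of the 13058 tested rows against the mean FPKM of the 6 libraries (log scale), with rows that passed adjusted p 0.05 in red (higher) and blue (lower) and the rest in grey. The dotted line marks the median of all tested rows at -0.11, and the points far below DNMT1 and BSG at high FPKM are small RNA rows.

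The largest increases were in genes that the control cells held at low levels. C1QTNF3, a secreted C1q and TNF related protein (chromosome 5, 34017963 to 34043371), went from 0.466 ± 0.079 to 45.7 ± 1.4 FPKM (SD, n = 3 per group), a 98.0-fold rise (log2 change 4.99, SE 0.055, limma adjusted p = 3.0e-10). IFI27, an interferon-inducible gene (chromosome 14, 94577079 to 94583033), rose 73.2-fold to 34.2 ± 0.79 FPKM. THBS2, a matrix thrombospondin (chromosome 6, 169615875 to 169654137), rose 26.5-fold to 38.2 ± 0.25 FPKM. SAA1, an acute phase protein, rose 30.5-fold, a fold that rests on uneven control values of 0.781, 1.67 and 0.476 FPKM. IL13RA2, a decoy receptor for interleukin 13, rose 41.5-fold, and CAPS, a calcium-binding protein whose row overlaps RANBP3, rose 25.8-fold. LAPTM5, a lysosomal membrane protein best known from leukocytes (chromosome 1, 31205315 to 31230683), was already at 8.02 ± 0.53 FPKM in the controls and rose 14.9-fold to 120 ± 0.73 FPKM. PAGE2B (chromosome X, 55101489 to 55105336) was listed at 0 in all 3 control libraries and at 15.1, 12.4 and 18.6 FPKM in siDNMT1. Its neighbour PAGE2 (chromosome X, 55115497 to 55119260) was listed at 0 in the controls and at 9.43, 9.34 and 10.5 FPKM. The pair are close paralogs, so reads may be split between them. APOC2, a cofactor of lipoprotein lipase, was listed at 0.0955, 0 and 0 FPKM in the controls and at 11.5, 12.6 and 13.6 FPKM in siDNMT1.

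The largest decreases included transcripts that fell as far as DNMT1. BSG, which encodes the membrane glycoprotein basigin (chromosome 19, 571277 to 583493), fell 9.98-fold from 274 ± 5.4 to 27.5 ± 2.8 FPKM (log2 change -3.28, SE 0.062, limma adjusted p = 2.3e-09). PPT2, a lysosomal thioesterase (chromosome 6, 32121229 to 32131458), fell 5.56-fold, B3GNT7, a glycosyltransferase, 5.03-fold, and SERTAD4 5.57-fold. CASK, a membrane-associated scaffold kinase, fell 11.9-fold from 4.43 ± 0.13 to 0.372 ± 0.051 FPKM. FZD7, a Wnt receptor, fell 3.89-fold, FAM84B 4.63-fold and DEPDC1 3.86-fold. The SERF1A rows were at 11.3, 2.83 and 8.51 FPKM in the controls and near 0.005 FPKM in siDNMT1. They share their loci with SERF1B rows of near-identical sequence, and the log2 change of the summed rows was -0.64, so the SERF1A value is uncertain. Among the named genes not said elsewhere to overlap another gene, the rows of C1QTNF3, APOC2, PPT2, SERTAD4, CASK, STAG3, CCNA2, PLK1, HOXA10, SHMT2 and HIST1H2BK do so, and those of LAPTM5, UHRF1 and H19 hold a microRNA row.

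Among 18 tested genes of the DNA methylation machinery, 11 fell, 0 rose and 7 did not pass, with the same counts adjusted over the list alone. UHRF1, which brings DNMT1 to replicated DNA, fell 1.99-fold from 22.7 ± 1.0 to 11.4 ± 0.60 FPKM, and PCNA, the replication clamp, fell 1.91-fold to 61.8 ± 2.5 FPKM; the PCNA row overlaps that of an antisense transcript. PCNA is also a member of the DNA replication and G1/S list. MECP2, a methyl-CpG binding protein, fell 1.71-fold. With median-ratio scaling 4 members rose and 9 fell, and with quantile normalization 3 rose and 9 fell; as TPM 4 rose and 9 fell. The list lay below other genes (camera, adjusted p = 0.040), but not with an estimated correlation (adjusted p = 0.15) and not when DNMT1 was left out of the list (adjusted p = 0.095), an alternative chosen after seeing the data. In these libraries MALAT1, NEAT1 and CD14 were 5.63-fold, 4.15-fold and 10.8-fold higher, and 12 of 14 housekeeping genes were lower.

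Genes of DNA replication and mitosis fell nearly throughout. In the DNA replication and G1/S list 38 of 39 tested members fell, 0 rose and CCNE1 did not pass, with the same counts adjusted over the list alone. The replicative helicase subunit MCM7 fell 2.38-fold from 118 ± 2.9 to 49.6 ± 2.2 FPKM, the helicase cofactor GINS2 2.88-fold, thymidylate synthase TYMS 2.29-fold and the origin licensing factor CDT1 2.60-fold. The MCM7 and TYMS rows overlap other genes. In the G2/M and mitosis list all 36 tested members fell, also when adjusted over the list alone. Cyclin A2 (CCNA2) fell 3.76-fold from 34.8 ± 1.2 to 9.26 ± 0.56 FPKM, the anaphase activator CDC20 3.16-fold, the mitotic kinase PLK1 2.96-fold and cyclin B2 (CCNB2) 2.66-fold. The median log2 changes were -0.98 and -1.10 as deposited and -0.84 and -0.95 with median-ratio scaling. Both lists lay below other genes with camera's preset correlation (adjusted p = 9.8e-12 and 2.2e-13) and with an estimated correlation (adjusted p = 0.038 for each). In the same libraries MALAT1 and NEAT1, of the RNA quality list, were 5.63-fold and 4.15-fold higher, CD14, a monocyte marker, was 10.8-fold higher, and 12 of 14 housekeeping genes were lower. Of the tested lists, 12 passed with the preset correlation, and those of type I interferon response, antigen presentation, inflammatory and senescence-associated secreted factors, G1/S and G2/M also passed with an estimated correlation.

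**Figure D3:**
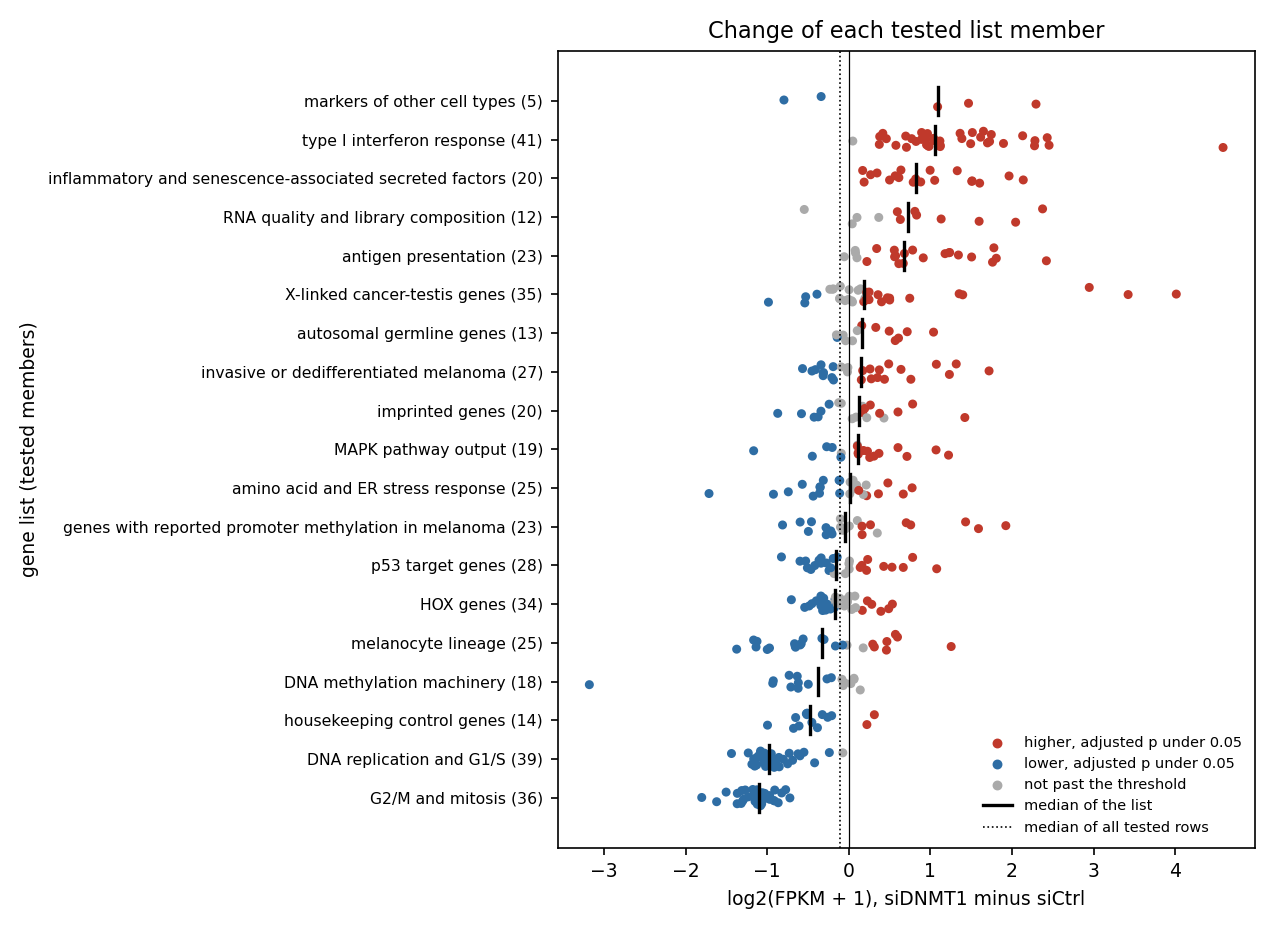
Log2 change (siDNMT1 minus siCtrl) of each tested member of the 19 tested gene lists, red or blue where limma's adjusted p was under 0.05, with a bar at the median of each list and a dotted line at the median of all tested rows. All 36 G2/M genes lie below 0, and 40 of 41 interferon response genes are red.

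Interferon response genes moved the other way. Of 41 tested members of the type I interferon list, 40 rose and IFITM2 did not pass, and the counts were the same adjusted over the list alone. ISG15, a ubiquitin-like modifier, rose 5.96-fold from 8.53 ± 1.7 to 50.8 ± 4.4 FPKM, IFI6 5.58-fold to 133 ± 8.9 FPKM and IFITM1, which restricts viral entry, 5.09-fold to 85.2 ± 1.5 FPKM. The median log2 change was 1.06 as deposited and 1.19 with median-ratio scaling (camera, adjusted p = 1.1e-24; adjusted p = 0.028 with an estimated correlation). In the same libraries the nuclear noncoding RNA MALAT1 was 5.63-fold higher and CD14 10.8-fold higher.

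Antigen presentation genes rose as well, with 19 of 23 tested members higher, 0 lower and 4 not past the threshold, and the same counts adjusted over the list alone. The class II chaperone CD74 rose 5.42-fold from 66.5 ± 5.2 to 360 ± 23 FPKM, and the class II genes HLA-DRA and HLA-DMA rose 3.54-fold and 3.51-fold. HLA-DPB1, whose row overlaps HLA-DPA1, rose 4.62-fold. The median log2 change was 0.68 as deposited and 0.82 with median-ratio scaling (camera, adjusted p = 7.7e-12; adjusted p = 0.038 with an estimated correlation). All 20 tested of 32 inflammatory and senescence-associated secreted factors rose, also adjusted over the list alone. The filter uses a mean that a rise itself lifts; without it 21 of 31 members rose and 0 fell, with a median log2 change of 0.57. The monocyte chemoattractant CCL2 rose 5.23-fold from 3.88 ± 0.81 to 20.3 ± 0.68 FPKM, interleukin 8 (IL8) 4.10-fold to 59.1 ± 2.5 FPKM, the apoptosis inhibitor BIRC3 11.5-fold from 0.241 ± 0.010 FPKM and the urokinase receptor PLAUR 2.89-fold. Their median log2 change was 0.82 as deposited and 0.95 with median-ratio scaling (camera, adjusted p = 7.7e-12; adjusted p = 0.038 with an estimated correlation). CD14 and MALAT1 were higher in the same libraries by the folds given above.

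Germline genes rose in part. Of 35 tested X-linked cancer-testis genes, which are normally silent outside the testis, 16 rose, 4 fell and 15 did not pass, with the same counts adjusted over the list alone. With median-ratio scaling and as TPM 22 rose and 4 fell; without the filter, which PAGE2 and PAGE2B passed through their siDNMT1 values, 32 of 70 rose and 4 fell, with a median log2 change of 0.15 against 0.18. Besides PAGE2B and PAGE2, CTAG2 rose 17.0-fold from 0.716 ± 0.25 to 12.2 ± 1.4 FPKM and PAGE5 2.86-fold to 20.1 ± 0.93 FPKM. The members that fell were MAGEA12, MAGEA3, MAGEA6 and CSAG1, outside the rule for named genes, and MAGEA3 and MAGEA6 are close paralogs. Many of the other members are near-identical copies whose reads cannot be told apart. The list lay above other genes (camera, adjusted p = 0.0015; adjusted p = 0.15 with an estimated correlation). Of 51 autosomal germline genes 13 were tested, of which 7 rose, 1 (PRAME) fell and 5 did not pass, and the counts were the same adjusted over the list alone. Their median log2 change was 0.16; without the filter, which HORMAD2, REC8 and STAG3 passed through their siDNMT1 values, 20 of 46 rose and 1 fell, with a median of 0.05. PRAME was not lower under median-ratio scaling (log2 change 0.01), as TPM (0.07) or with quantile normalization (0.06). HORMAD2, a meiotic chromosome axis protein, went from 0.0722 ± 0.026 to 1.21 ± 0.29 FPKM, and the meiotic cohesin subunits REC8 and STAG3 reached 0.996 ± 0.18 and 0.911 ± 0.078 FPKM, with REC8 overlapping IPO4. GTSF1 rose 2.27-fold. MALAT1 (5.63-fold) and CD14 (10.8-fold) were higher in the same libraries. The list test gave an adjusted p of 0.017 with camera and an adjusted p of 0.23 with an estimated correlation.

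Lineage genes of the melanocyte were divided. Of 25 tested members 16 fell, 7 rose and 2 did not pass, also adjusted over the list alone, and 14 fell and 8 rose with median-ratio scaling. The pigment cell transporter SLC45A2 fell 2.69-fold from a mean of 43.1 ± 1.4 FPKM, RAB38, which carries cargo to melanosomes, 2.31-fold and the pigment enzyme DCT 2.35-fold, while the protease CAPN3 rose 2.62-fold to 15.6 ± 1.3 FPKM. GPNMB fell as deposited and was higher under median-ratio scaling, as TPM and with quantile normalization, and ST3GAL6 was not lower as TPM or with quantile normalization. The list did not differ from other genes (camera, adjusted p = 0.32; 0.59 with an estimated correlation). Of 27 tested genes of invasive or dedifferentiated melanoma 14 rose, 10 fell and 3 did not pass, also adjusted over the list alone (camera, adjusted p = 0.017; adjusted p = 0.12 with an estimated correlation). With median-ratio scaling 16 rose and 7 fell, as with quantile normalization, and as TPM 16 rose and 4 fell. Without a filter the list did not pass (adjusted p = 0.088), with a median log2 change of 0.02 over 29 members against 0.15. MALAT1, NEAT1, CD14 and KRT8 were 5.63-fold, 4.15-fold, 10.8-fold and 5.68-fold higher in the same libraries. Of 5 tested markers of other cell types 3 rose and 2 fell, among the latter KRT18 (1.81-fold), whose row overlaps KRT8. The matrix protein TGFBI rose 3.50-fold to 39.0 ± 1.1 FPKM, the plasminogen activator inhibitor SERPINE1 2.54-fold to 85.6 ± 3.8 FPKM and the matricellular genes CTGF and CYR61 2.37-fold and 2.28-fold. With TPM or quantile normalization VIM was not lower (log2 change 0.03 and 0.38), and as TPM neither were CDH2 and ZEB1 (0.01 each).

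Among 19 tested genes of MAPK pathway output, 12 rose, 5 fell and 2 did not pass (13 and 6 adjusted over the list alone). The counts were 13 higher and 3 lower with median-ratio scaling, 13 and 2 as TPM and 14 and 2 with quantile normalization. MALAT1, CD14 and the housekeeping genes moved in these libraries as given above. The receptor kinase EPHA2 rose 2.43-fold to 35.2 ± 1.5 FPKM, and the immediate early genes FOS and EGR1 rose 2.71-fold and 1.66-fold, while MYC fell 2.29-fold from 60.6 ± 1.8 to 26.4 ± 1.5 FPKM. The list test passed with the preset correlation (camera, adjusted p = 0.0095) and not with an estimated one (adjusted p = 0.28). The log2 change of PHLDA1, lower as deposited, was above 0 under the 3 other scalings, and that of ETV5 as TPM and with quantile normalization. Of 28 tested p53 target genes 9 rose and 14 fell as deposited, also adjusted over the list alone, and 9 rose and 9 fell with median-ratio scaling, 10 and 6 as TPM and 11 and 10 with quantile normalization. The stress-induced TP53INP1 rose 2.33-fold, the ribonucleotide reductase subunit RRM2B 1.77-fold and SESN2 1.70-fold, while cyclin G1 (CCNG1) fell 1.79-fold. The median and mean log2 changes were below 0 (-0.16 and -0.05), camera placed the list above other genes without passing (adjusted p = 0.84; adjusted p = 0.89 with an estimated correlation), and fry, which does not compare with other genes, gave a lower direction (adjusted p = 0.026). PHLDA3, lower as deposited, was not lower as TPM or with quantile normalization, nor were BBC3 as TPM and GDF15 with quantile normalization.

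Of 20 tested imprinted genes 7 rose, 6 fell and 7 did not pass, also adjusted over the list alone, and 11 rose and 5 fell with median-ratio scaling and 12 and 4 as TPM. Their median log2 change was 0.13, and 0.01 over 31 members without a filter. MEST rose 3.84-fold to 5.55 ± 0.39 FPKM, the noncoding RNA H19 1.74-fold to 84.8 ± 4.4 FPKM and SLC22A18 1.54-fold, while the cell cycle inhibitor CDKN1C fell 2.32-fold. MEST and SLC22A18 overlap other expressed rows. Among 23 tested genes with reported promoter methylation in melanoma 8 rose, 8 fell and 7 did not pass, also adjusted over the list alone, and 8 rose and 6 fell with median-ratio scaling and 9 and 4 as TPM. The cytokine signalling inhibitor SOCS3 rose 9.44-fold to 4.65 ± 0.28 FPKM, the protease inhibitor TFPI2 3.38-fold to 18.2 ± 1.2 FPKM and the collagen chain COL1A2 2.70-fold, and the inflammasome adaptor PYCARD fell 1.81-fold. The median of this list was -0.04 and its mean 0.16, and PRDX2 was not lower as TPM. Of 34 tested HOX genes 6 rose, 15 fell and 13 did not pass (6 and 14 adjusted over the list alone), and 10 rose and 9 fell with median-ratio scaling and 10 and 4 as TPM. HOXA3 was not lower as TPM. HOXA4 fell 1.74-fold and HOXD13 1.63-fold, while HOXA10 rose 1.48-fold and HOXD1, whose row overlaps an antisense RNA, rose from 0.571 ± 0.14 FPKM by a log2 change of 0.49. Camera did not separate these lists from other genes (adjusted p = 0.14 for imprinted genes, 0.24 for methylated promoters and 0.84 for HOX genes; with an estimated correlation adjusted p = 0.32, 0.54 and 0.89).

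Of 25 tested genes of the amino acid and ER stress response 6 rose and 12 fell (8 and 12 adjusted over the list alone), and 12 rose and 8 fell with quantile normalization, 13 and 5 as TPM, and 13 and 8 with median-ratio scaling, under which the log2 changes of ATF4, HSP90B1 and XBP1 turned from below to above 0, as they did as TPM and with quantile normalization. The amino acid transporter SLC7A5 fell 3.49-fold from 37.6 ± 2.0 to 10.8 ± 0.55 FPKM, the serine pathway enzymes SHMT2 and PHGDH fell 1.92-fold and 1.69-fold, and CHAC1 rose 2.15-fold. The median of the list was 0.01, its mean -0.11, and camera gave no difference (adjusted p = 0.81; 0.89 with an estimated correlation). Of the endogenous retrovirus-derived genes 1 passed the filter, ERVK13-1, which went from 0.680 ± 0.041 to 0.940 ± 0.079 FPKM (limma adjusted p = 0.024), with too few members for a list test. That call was lost without siCtrl replicate 01 (adjusted p = 0.057), siDNMT1 replicate 01 (0.061) or siDNMT1 replicate 02 (0.059) and with quantile normalization (0.42), while its log2 change was 0.21 in all libraries, 0.19 without each of these 3 and 0.07 with quantile normalization.

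The control lists were not level. Of 14 housekeeping genes 12 fell and 2 (GUSB and POLR2A) rose, also adjusted over the list alone, with a median log2 change of -0.48 as deposited and -0.33 with median-ratio scaling. YWHAZ fell 2.00-fold from 516 ± 18 to 258 ± 5.4 FPKM, ACTB from 1708 ± 41 to 1067 ± 27 FPKM, RPLP0 1.57-fold and RPL13A, which shares its locus with a pseudogene row, 1.53-fold; these 4 were lower under each scaling, while UBC was not lower as TPM (log2 change 0.01). The list lay below other genes (camera, adjusted p = 0.016; adjusted p = 0.35 with an estimated correlation). The RNA quality and library composition list had 22 members, of which 13 had a row and 12 were tested. Of the 12 tested, 8 rose, 0 fell and 4 did not pass, also adjusted over the list alone (camera, adjusted p = 4.0e-05, and adjusted p = 0.091 with an estimated correlation). MALAT1 rose from 9.43 ± 0.48 to 53.1 ± 2.9 FPKM, NEAT1, another nuclear noncoding RNA, 4.15-fold, and the histone genes HIST2H2AA3 and HIST1H2BK 3.65-fold and 2.25-fold. HIST2H2AA3 has an identical copy. Of 23 markers of other cell types 5 passed the filter, of which 3 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.096; 0.23 with an estimated correlation). CD14 reached 7.09 ± 0.19 FPKM, the T cell gene CD3E rose 5.01-fold to 1.98 ± 0.36 FPKM, and the epithelial keratin KRT8 rose 5.68-fold to 3.43 ± 0.084 FPKM while its overlapping partner KRT18 fell 1.81-fold to 9.65 ± 0.92 FPKM. CD3E stood at 0.395 ± 0.056 FPKM in the controls and passed the filter through its siDNMT1 values.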

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

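Leaving out small RNA rows, rows with a failed estimate or DNMT1 from its list, and removing the length trend, were alternatives chosen after the results were seen. The DNMT1 decrease passed the threshold under all 21 alternatives run for it, with log2 changes from -3.40 to -3.04 and limma adjusted p from 2.0e-16 to 1.4e-06. Of the other 93 named rows, 92 kept their direction and their call under each alternative run for them, and ERVK13-1 lost its call under 5. The rule picked these rows for large changes past the threshold, so their stability does not extend to the other calls. Of the 6015 rows called lower as deposited, 3135 were called lower as TPM. Leaving out each library gave 2895 to 3056 genes higher and 5661 to 5883 lower, and 340 to 365 higher and 247 to 275 lower by at least 1 log2 unit. At least 1 log2 unit was reached by 630 higher and 456 lower genes with a pseudocount of 0.1, which by construction widens the changes of low genes. With a filter at a mean of 5 FPKM, where fewer genes were tested, 1841 genes were higher and 191 higher by at least 1 log2 unit. As TPM 3136 genes were lower, 717 higher by at least 1 log2 unit and 160 lower by as much. TPM values were larger than the FPKM while the pseudocount stayed at 1, which by itself widens the changes of low genes. The totals used for TPM also included the small RNA rows, so the TPM counts depend in part on those rows. A pseudocount of 0.5 on FPKM gave 472 higher and 337 lower by at least 1 log2 unit. The count lower by at least 1 log2 unit was 147 with median-ratio scaling, 163 with quantile normalization and 141 with the length trend removed. The replicate block gave 3052 higher and 5843 lower genes, and 354 and 258 by at least 1 log2 unit; among the named rows it ended the call of ERVK13-1 alone (adjusted p = 0.0502). The replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at -0.0693, 0.0508 and -0.142, and 1 of 6 libraries correlated best with its own number in the other group.

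Of 436 list tests under alternatives, 411 kept their side of the threshold and their direction. With an estimated correlation the adjusted p became 0.154 for DNA methylation machinery and for X-linked cancer-testis genes, 0.228 for autosomal germline genes, 0.115 for invasive melanoma genes, 0.277 for MAPK output, 0.346 for housekeeping genes and 0.0907 for RNA quality. Fry, which does not compare a list with other genes, gave an adjusted p of 0.000107 for melanocyte lineage, 0.0139 for imprinted genes, 0.00354 for methylated promoters, 0.00776 for HOX genes, 7.25e-06 for markers of other cell types, and the opposite direction for p53 targets (0.0261) and the amino acid and ER stress response (0.0136). Without a filter the adjusted p was 0.0877 for invasive melanoma genes and 0.0477 for markers of other cell types, and p53 targets (0.677) and the amino acid and ER stress response (0.804) turned downward. It was 0.0689 for DNA methylation machinery and 0.119 for autosomal germline genes at a filter of 1 FPKM, and 0.0624 for DNA methylation machinery and 0.0593 for housekeeping genes at 5 FPKM. Quantile normalization gave 0.180 for autosomal germline genes. HOX genes turned upward with the length trend removed (0.557), and DNA methylation machinery without DNMT1 gave 0.0945. Except where a cause is given, causes were not tested. FPKM keep no counts, so what depth limits could not be set in reads. Rows with a mean under 0.5 FPKM were left untested in the main fit.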

Other observations

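The gene families and the switched-on genes of this part, and the alternatives that leave out small RNA rows or remove a length trend, were chosen only after the data were seen; the bounds of each test of an explanation were set before its result was seen. Collagen genes formed a group not covered by the report. Of 26 tested, 21 rose and 2 (COL22A1 and COL18A1) fell, with a median log2 change of 0.87 as deposited and 1.01 with median-ratio scaling. In the same libraries MALAT1 was 5.63-fold, NEAT1 4.15-fold, CD14 10.8-fold, CD3E 5.01-fold and KRT8 5.68-fold higher. Of the 5 tested markers of other cell types 3 rose and 2 fell, among the latter KRT18 (1.81-fold). COL11A2 rose from 3.07 ± 0.033 to 36.9 ± 1.2 FPKM (SD, n = 3), COL6A1 from 206 ± 5.1 to 564 ± 32 FPKM and COL4A3 from 1.72 ± 0.15 to 5.35 ± 0.15 FPKM. Of 11 S100 calcium-binding protein genes 9 rose and 2 (S100A10 and S100A11) fell, with S100A4 going from 151 ± 7.3 to 408 ± 24 FPKM. Of 44 protocadherin genes 20 rose and 8 fell (25 and 6 with median-ratio scaling, 25 and 4 as TPM), and PCDHGA3, a member of a cluster whose genes share their last exons, rose from 0.408 ± 0.10 to 3.90 ± 0.056 FPKM. All 6 tested metallothionein genes, which bind zinc and copper, fell, MT1X from 25.3 ± 1.0 to 7.75 ± 1.0 FPKM and MT2A from 547 ± 20 to 351 ± 7.5 FPKM. Genes of protein synthesis were lower too. Of 83 cytosolic ribosomal protein genes 80 fell as deposited, 74 with median-ratio scaling, 59 as TPM and 56 with quantile normalization, and of 79 mitochondrial ones 72 fell as deposited and 52 as TPM. These families passed camera with the preset correlation (adjusted p = 2.1e-11 for collagens, 0.00064 for S100, 0.0017 for protocadherins, 0.012 for metallothioneins, 1.5e-12 and 6.3e-10 for the ribosomal families), and none of them with an estimated correlation (adjusted p from 0.12 to 0.21). In all 13 families were computed. With the preset correlation 32 histone genes (11 higher and 4 lower, 0.0049), 37 proteasome genes (1 and 34, 3.5e-07), 37 complex I genes (0 and 31, 0.00057), 31 V-ATPase and cathepsin genes (15 and 9, 0.015) and 56 LINC rows (22 and 11, 0.0032) also passed. With an estimated correlation these gave 0.21, 0.21, 0.21, 0.38 and 0.12. As TPM complex I had 3 higher and 12 lower. At the preset correlation 431 zinc finger (ZNF) genes, with 62 higher and 158 lower (0.82), and 190 solute carrier genes, with 67 higher and 76 lower (0.12), did not. With median-ratio scaling these counts were 105 and 83 for zinc finger and 89 and 50 for solute carrier genes, and as TPM 111 and 48, and 89 and 41. With quantile normalization they were 53 and 143, and 80 and 54. None of the 13 passed with an estimated correlation.

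Outside small RNA rows, chromosome Y and XIST, 13 rows lay at or under 0.1 FPKM in each control library and at or above 1 FPKM in each siDNMT1 library. They were APOC2, COL11A1, CPLX3, IL18, NR5A1, OTOR, PAGE2, PAGE2B, RFPL4B, SFN, STAB1, TNF and UROC1. OTOR, listed at 0 in each control, was at 1.26, 1.71 and 1.92 FPKM in siDNMT1. CPLX3 went from 0.0262, 0 and 0 to 1.43, 1.65 and 1.39 FPKM, and IL18 from 0.00397, 0 and 0 to 1.91, 3.81 and 2.27 FPKM. SFN went from 0, 0.0457 and 0 to 1.79, 2.09 and 1.53 FPKM, and UROC1 from 0, 0.0141 and 0 to 3.04, 2.96 and 3.00 FPKM. An exact 0 can be a failed estimate. NR5A1, a nuclear receptor of steroid-producing tissues, was at 0.0325, 0 and 0.0169 FPKM in the controls and at 3.69, 2.91 and 3.29 FPKM in siDNMT1. TNF, the inflammatory cytokine, reached 1.80, 1.37 and 1.94 FPKM. The reverse pattern was met by the uncertain SERF1A rows alone.

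BSG fell as far as DNMT1, and 258 rows in all fell by at least 1 log2 unit. Reads moving between overlapping or same-named rows would need a partner row, and 74.42% of the fallen rows (192) had none. After summing with partners the median log2 change of the 258 was -1.14 against -1.17 before, and 237 stayed lower by at least 1 log2 unit. Summing cannot change the 192 rows without a partner, so this median and count say little about the rows with one. Among the 21 that did not stay lower, all with a partner, the summed change was 0.23 for RFC4, -0.05 for LOC100128881, -0.21 for LRRN3, -0.25 for RAD54L, -0.38 for FAM20A, -0.41 for DHFR and -0.64 for SERF1A, so moved reads stay open for those rows. Seed-matched silencing by the siRNA pool, whose sequences were not used here, stays open. The 4 7-base sites of the DNMT1 transcript most tied to lower values among the other genes were carried in the 3' UTR by 66.2% of the fallen genes. For their UTR length 57.9% was expected, a ratio above 92.7% of 1000 random sets, between the bounds set in advance. The sites (TTTTTAA, TTTTTTA, TTTTAAA and TTTAAAA) were overlapping runs of T and A, each carried by 5497 to 6049 genes. The ratio therefore cannot tell siRNA seeds from the base composition of the 3' UTRs. A response to the loss of DNMT1 is the biological explanation that the design offers, and it cannot be told apart from seed-matched silencing with 1 siRNA pool.

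Among the rows that rose were 5 genes best known from leukocytes, picked after seeing that they rose and not tested as a group: LAPTM5, FCER1G (2.29 ± 0.33 to 18.5 ± 1.2 FPKM), SRGN (1.93 ± 0.23 to 13.6 ± 0.64 FPKM), CD14 and CST7. RNA of contaminating leukocytes would bring their abundant transcripts, and the median of 20 such genes, listed before the test, was at most 0.3028 FPKM in a siDNMT1 library, under the bound of 1 FPKM set in advance. It was nonetheless higher there (0.222 to 0.303 FPKM) than in the controls (0.0568 to 0.0821 FPKM), so the test argues against leukocyte RNA as the source of the rise without excluding traces. PTPRC stayed under 0.01 FPKM, and S100A8 and S100A9 were listed at 0 in each library. CD52 (22.4 to 27.3 FPKM), CD53, CD68 and TYROBP were higher in siDNMT1, as were CD37, HCLS1, ITGB2, LST1 and LYZ, each under 1 FPKM in every library. CORO1A (0.523 to 0.553 against 1.07 to 1.46 FPKM), LSP1 (1.16 to 1.86 against 3.12 to 3.66) and LCP2 (8.78 to 9.57 against 10.2 to 10.9) were lower. The list shares PTPRC and LYZ with the markers of other cell types, and 2 or 3 of its genes were at 5 FPKM or more in each control library and 4 in each siDNMT1 library. With the trend on transcript length removed, the median log2 change of the 5 genes was 2.521 against 2.317 before. Removing it did not lessen the rise, so that trend did not account for it, although the step also centres each library. Expression of these genes by the melanoma cells after DNMT1 loss is a hypothesis that the tests leave standing, found and tested on the same data.

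More rows fell than rose in FPKM as deposited. Transcript length alone would turn the direction in some length class, but the median log2 change was -0.18, -0.14, -0.10 and -0.08 (highest -0.07632) from the shortest to the longest of 4 classes. The trend is there, and the values argue only against length as the whole cause. With it removed the counts were 4540 higher and 4464 lower, but that step also centres each library. A few genes taking more of the fragments stays open. The 20 rows that gained most gained 4.187% of the FPKM-weighted length, between the bounds set in advance. By this weighting SERPINE2 (0.945%), NEAT1 (0.682%) and FN1 (0.648%) led. Each row was weighted by its longest GENCODE transcript. The NEAT1 row covers only 65190269 to 65194003 of chromosome 11, shorter than that transcript, so its gain and the total are overstated. Median-ratio scaling and the removal of the length trend centre the genes, so their even splits test nothing here. Whether the cells' total RNA changed cannot be read from FPKM.

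With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 3175 higher and 6015 lower genes, and 354 and 258 by at least 1 log2 unit, each reached by 1 split, the real one, and the highest count of any other split in either direction was 1. Every other split mixed siCtrl and siDNMT1 libraries on each side, so the group difference widened the spread within its sides. Low counts were to be foreseen there, and they do not measure the rate of false calls.

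Because X-linked cancer-testis genes were among the largest increases, it was tested whether rows of the X chromosome rose by at least 1 log2 unit more often than other rows. Without the cancer-testis list 7 of 451 X rows (1.55%) did, against 341 of 12552 others (2.72%), an odds ratio of 0.5646 (95% interval 0.224 to 1.19, Fisher's exact test, two-sided, p = 0.18). With the list it was 12 of 494 rows. More frequent rises of that size on the X chromosome were therefore not seen, although rows that are neighbours are not independent. A smaller rise across the chromosome would not reach 1 log2 unit and was not tested.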
